A study of Mus musculus with 9 samples.

How the data were processed

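RNA was measured on 9 Affymetrix mouse gene arrays, 3 for each of 3 cultures of cells from the embryonic cortex of CD1 mice. Per the labels, neurons were taken on embryonic day 16 and kept for 5 days in total, precursors were taken on embryonic day 13 and kept for 1 day, and in the co-culture precursors were added to neurons after 4 days and kept with them for 1 day. One label gives 4 days for the neurons alone and another 5 days in total; the total is used here. Per the labels, cDNA was made from 100 ng of total RNA with a whole-transcript kit. The labels call the arrays biological replicates 1 to 3 of each group. Which embryos, litters or days a number stands for is not given in the sources used here.

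The deposited values are log2 levels per probe set, made by the authors with RMA in the oligo package, per the submitters' processing notes, with no versions named. RMA as such corrects background, makes the arrays' distributions alike and summarises the probes of a probe set by a robust fit over all arrays. Scanner files and probe-level values were not analysed here. The array medians lay between 6.75 and 6.79 and the values between 2.95 and 13.9 on the log2 scale. Array data have no read depth, so the number of arrays limits the precision. No detection calls were used, so folds of genes near the dim end of the scale can be understated.

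Of 41345 probe sets, 23521 had 1 gene symbol in the platform table, 1814 had several and 16010 had none; only those with 1 symbol were used. Of the probe sets with 1 symbol, 23328 matched the mouse gene table of assembly GRCm38.p6 by gene number, and 0 symbols changed. No genome build is named for the values, so no coordinates are printed. The probe set with the highest mean stood for each of 22180 genes, of which 1082 had more than 1 probe set. Genes above the array median of all probe sets in at least 3 arrays were tested, which left 13012.

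One limma model (version 3.58.1, R 4.3.3) was fitted to the 3 groups, with lmFit and eBayes, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Tests are two-sided except the test for levels outside both separate cultures, which took the larger of 2 one-sided p-values per gene, and the comparison of the immediate early genes high in neurons with matched gene sets, which was one-sided. The neuron share of the co-culture RNA was computed per gene on the linear scale, as the co-culture level minus the precursor level over the neuron level minus the precursor level. It was taken as the mean of 2 medians, over genes at least 4-fold higher in neurons and over genes at least 4-fold higher in precursors. Each gene's co-culture level was then compared with the level that mixing at this share would give, with a contrast specific to the gene; the error of the share itself is not part of that test. A total of 29 gene lists with 577 entries were tested with camera at a preset correlation of 0.01 between genes, and with an estimated correlation beside it. Against the predicted mixture the estimated correlation was taken as known, which makes that check less strict. For 534 entries a named probe set was present and 420 were tested. The adjustment ran over all lists and 4 contrasts.

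The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule names, per comparison, the 8 genes with the largest rise and the 8 with the largest fall past the threshold whose groups do not overlap, up to 4 members of each list with the largest difference, the 10 genes farthest from the predicted mixture in each direction, and 40 ligands, receptors and markers. Of these 40, 36 had a named probe set in the table used here, and not all of the 40 are reported here. By chance, 10% of genes have groups of 3 that do not overlap.

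Same-numbered precursor and co-culture arrays deviated from their group means together, with correlations across genes of 0.34, 0.30 and 0.16 for numbers 1 to 3. By the rule set beforehand (every pair above 0.1) the numbers pair these 2 groups. They do not pair neurons with precursors (0.0043, 0.13 and -0.15) or with the co-culture (-0.0051, 0.27 and 0.17).

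On simulated arrays with the spread of the 13012 tested genes, 96.3% of genes changed 1.5-fold between neurons and precursors were called with the right sign, and 1.01% of the calls were false. For co-culture against precursors 95.1% of genes changed 1.5-fold were called. Of genes raised 1.5-fold above both separate cultures 95.6% were called. There, simulated neurons and precursors had the same levels, and many genes changed at once in the whole co-culture RNA. The rate does not cover a change in few genes or within only 1 of the mixed cell types. A share of 20% was recovered as 20.3%, and 98.8% of genes moved 1.5-fold off the predicted mixture were called, with 5.24% of the calls false. The noise of this simulation was the same in all groups. For the share and the predicted mixture, the simulated co-culture was mixed by the formula that the test assumes, with a single share. Both directions recovered that share (20.1% and 20.4%). In the data the directions gave 22.6% and 10.97%, so the simulated rate of false calls does not cover that departure.

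Alternatives were other filters on dim probe sets, the mean of a gene's probe sets, cyclic loess, arrays centred on their median, a trended robust variance, array weights, fits to only the 2 groups compared, stricter thresholds, the replicate number as a block, each array left out in turn, other genes or a background for the share, other shares for the mixture, and fry for the lists. These alternatives were chosen after seeing the data: the spread taken from the separate cultures alone, a share specific to each gene's direction, and, for the lists shifted against the mixture, 10000 gene sets matched on the difference of neurons from precursors and on the precursor level, with p-values adjusted over these 5 lists.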

Results

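The data are expression levels in 3 cultures from the developing mouse cortex, with 3 arrays each: neurons alone, proliferating precursors alone, and precursors grown for 1 day on neurons. The series concerns growth factor signals between these cells, so the levels of ligands and receptors are given beside those of cell type markers. Levels are log2 RMA values of 13012 tested genes. The p-values measure the spread between 3 biological replicates per group. Over all probe sets, arrays of 1 group correlated at 0.988 or above, neurons with precursors at 0.964 to 0.969, and precursors with the co-culture at 0.989 to 0.994. The first principal component held 87.3% of the variance. Neurons lay between 42.4 and 44.9 on it, precursors between -29.1 and -28.2 and the co-culture between -16.0 and -14.4.

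The first comparison asked how neurons and precursors differ. Genes of dividing cells and of radial precursors were lower in neurons, and genes of synapses were higher. All 26 tested cell cycle genes and 19 of 20 radial precursor genes were lower, but with an estimated correlation between genes neither list passed (adjusted p = 0.286 and 0.203, camera), while the synapse list, with 20 of 21 genes higher, did (adjusted p = 0.0401). Mki67, a marker of cycling cells, was at 7.32 ± 0.25 (SD, n = 3) in neurons and 10.27 ± 0.031 in precursors, a 7.77-fold difference (adjusted p = 1.14e-08, limma). Sox2, a transcription factor of neural stem cells, was at 8.13 ± 0.21 and 10.08 ± 0.088, and Pax6, a transcription factor of radial precursors, at 6.98 ± 0.30 and 9.01 ± 0.071. Necab1, which encodes a neuronal calcium-binding protein, was 23.7-fold higher in neurons (log2 difference 4.57, SE 0.049). Tubb3, a tubulin of young neurons, was at 11.95 in neurons and 11.96 in precursors, a difference of -0.0083 (SE 0.042, adjusted p = 0.880) that did not pass the test.

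**Figure D1:**
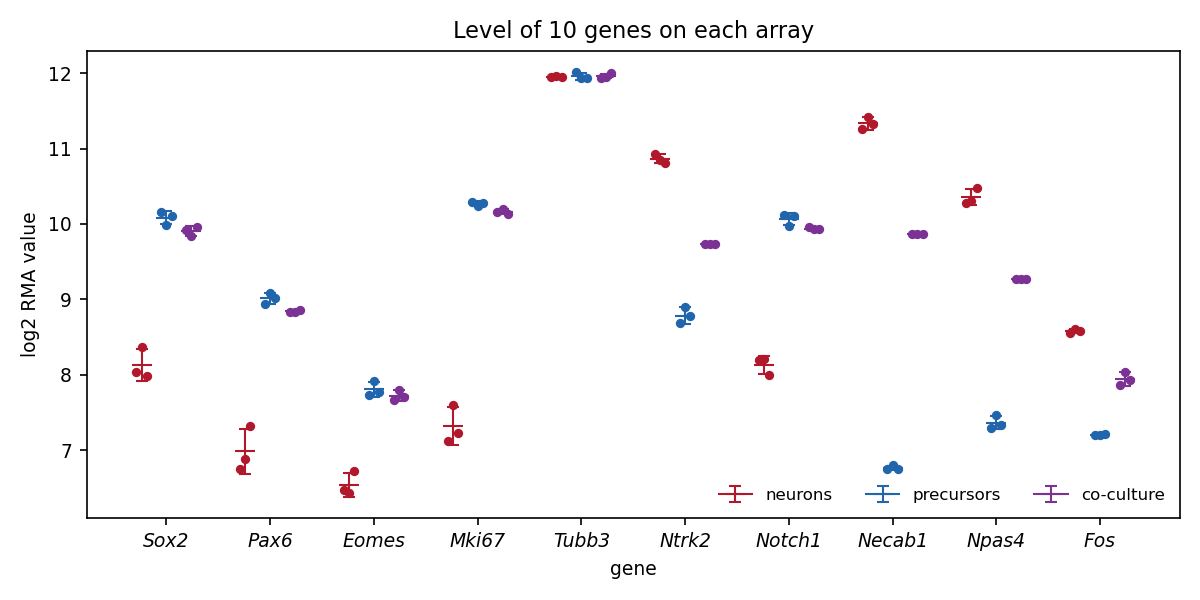
Log2 RMA values (vertical axis) of 10 genes in neurons, precursors and the co-culture; points are single arrays, and bars give the mean and SD of 3. Mki67, Sox2, Pax6, Eomes and Notch1 are lowest in neurons, Ntrk2, Necab1, Npas4 and Fos are highest in neurons with the co-culture between, and Tubb3 has means of 11.95 to 11.96 in the 3 cultures.

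The cell cycle list had a median log2 difference of -2.30 in neurons; Top2a was 8.44-fold and Bub1 7.72-fold lower. Of 20 radial precursor genes 19 were lower (median -1.29), led by Gli3 at -2.82 and Hmga2 at -2.44. Of 10 intermediate progenitor genes 9 were lower, among them Eomes at -1.27. In the Notch pathway list 14 of 19 genes were lower and 3 higher, with Notch1 at -1.93, Lfng at -1.88 and Jag1 at -1.73. These lists passed camera with the preset correlation (adjusted p = 4.64e-13, 9.53e-08, 9.45e-04 and 0.0068). With an estimated correlation none of these did (adjusted p = 0.286, 0.203, 0.251 and 0.165). Of 21 synapse and excitability genes 20 were higher in neurons (median 1.30), with the glutamate receptor subunits Grin2a at 2.81 and Grin2b at 2.19 and the sodium channel Scn2a at 2.21. This list passed with both correlations (adjusted p = 7.67e-10 preset and 0.0401 estimated). Of 16 early neuron genes 12 were higher and 1 lower; the neurofilament gene Nefl differed by 1.60 and Mapt by 1.42 (adjusted p = 6.52e-04, and 0.0652 with an estimated correlation). Adjusted over the list alone, the counts of changed genes were 26, 19, 9, 17, 21 and 13 in these lists.

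Several chemokine and cytokine genes were higher in the precursor cultures. Ccl3, a chemokine made by macrophages and microglia, was 17.1-fold higher in precursors than in neurons, Il1a 6.40-fold, Ccl5 4.38-fold and Il1b 4.25-fold. The cytokine ligand list did not shift as a whole (6 lower and 3 higher in neurons of 15, and 8 changed adjusted over the list alone; adjusted p = 0.535). The microglia and macrophage list did not shift either, with 3 of 8 genes lower and 1 higher, and 4 changed adjusted over the list alone (adjusted p = 0.680); Fcer1g, an Fc receptor subunit of myeloid cells, was 2.01-fold lower in neurons and Aif1, another myeloid marker, was higher at 0.41. Slc7a11, a cystine transporter, was 13.4-fold lower in neurons and Nhlh1, a transcription factor of newborn neurons, 10.8-fold. The histone genes H1f5 (27.7-fold lower) and H2bc12 (10.7-fold lower) belong to families of near-identical copies, and their probe sets can also pick up other copies. Among the neuron arrays, replicate 2 had the highest H1f5 (5.82 against 4.64 and 4.50) and Slc7a11 (6.85 against 6.14 and 6.16), and also the highest Mki67 (7.60 against 7.12 and 7.22) and Top2a (7.34 against 7.10 and 6.89), genes singled out after their values were seen.

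Growth factor genes moved in both directions. The receptors of neurotrophins and GDNF were higher in neurons in 8 of 9 cases, with Ntrk2 4.23-fold, Gfra2 2.54-fold and Ntrk3 at 0.72, and Gfra1 was lower (-0.30); adjusted over the list alone 9 changed, and the list had adjusted p = 0.00556, and adjusted p = 0.273 with an estimated correlation. Lifr, a receptor for LIF-type cytokines, was 2.25-fold higher and Ifngr2, a subunit of the interferon gamma receptor, 1.73-fold higher in neurons. Ifngr1 (-0.33, adjusted p = 0.0147) and Il6st (-0.29, adjusted p = 0.0161) were lower, but Ifngr1 did not pass without neuron replicate 1 (0.0509) or precursor replicate 1 (0.0558), nor Il6st without neuron replicate 1 (0.0616), neuron replicate 3 (0.0581) or precursor replicate 3 (0.0614). The FGF receptors Fgfr1, Fgfr2 and Fgfr3 were lower in neurons by log2 values of -1.21, -0.53 and -1.06, while Met was 4.58-fold and Erbb4 3.68-fold higher; of the 24 FGF, EGF, PDGF, IGF and VEGF receptors 15 were lower and 5 higher, 20 changed adjusted over the list alone, and the list did not shift (adjusted p = 0.187). Among the matching ligands 18 of 29 were higher in neurons and 4 lower, with 22 changed adjusted over the list alone (adjusted p = 0.00831, and adjusted p = 0.325 with an estimated correlation). Fgf12, Nrg3 and Pdgfa were higher at 2.11, 2.06 and 0.65, and Mdk, Fgf15, Nrg1 and Vegfa were lower at -2.64, -1.69, -0.88 and -0.71. Clcf1 (-0.73), Bmp7 (-0.62) and Wnt7a (-0.57) were lower in neurons, and Wnt7b (0.37) was higher. Ret (0.43), Egfr (0.36) and Pdgfc (0.33) were higher. Nrtn (-0.094), Ctf1 (0.13), Tgfb2 (0.037) and Igf2 (-0.37, adjusted p = 0.0783) did not pass the threshold, though Igf2 did without co-culture replicate 2 (adjusted p = 0.00616). Bdnf, at 6.62 ± 0.16 in neurons and 6.18 ± 0.068 in precursors, was below the filter and untested, as were Gdnf, Ifng, Fgf2 and Pdgfra.

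**Figure D2:**
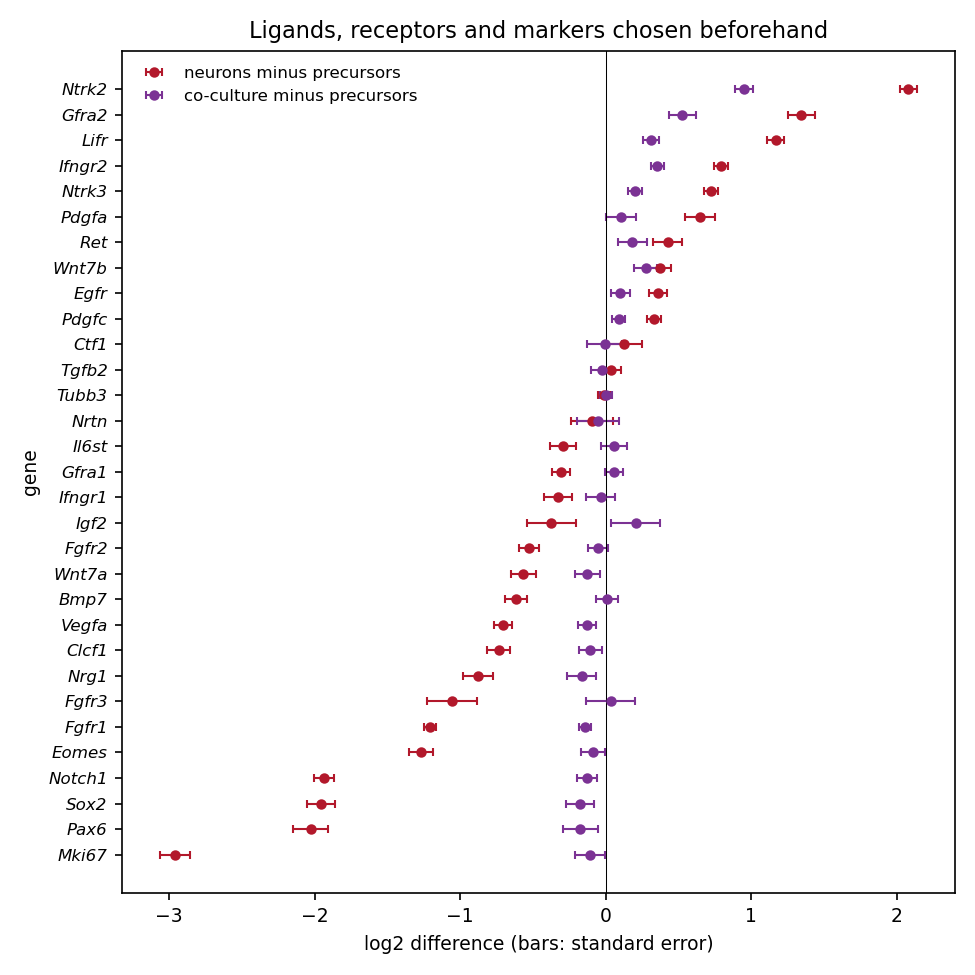
Log2 differences of the tested ligands, receptors and markers chosen beforehand, neurons minus precursors and co-culture minus precursors; bars are standard errors of the limma fit. Ntrk2 (2.08) and Gfra2 (1.34) have the largest positive differences in neurons and Mki67 (-2.96) the largest negative one, and the co-culture differences lie nearer 0.

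In all, 3637 genes were higher and 4574 lower in neurons than in precursors, and 715 and 624 of these differed at least 2-fold. With centred arrays 4189 were higher and 4081 lower, and with cyclic loess 4138 and 4189, so that 50.7% and 49.7% of the calls were higher in place of 44.3%. The neuron and precursor cultures also differed in embryonic day and in time in culture.

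The co-culture was compared with precursors to find levels that differ where neurons are present, whose own RNA is part of the sample. Necab1 was 8.60-fold, Vsnl1 4.62-fold and Gabrb1 4.06-fold higher than in precursors, and the activity-dependent transcription factors Npas4 and Nr4a3 were 3.75-fold and 4.02-fold higher. Of the synapse genes 17 of 21 were higher (median 0.43), with Grin2b at 0.88 and Gria1 at 0.88. Of 17 immediate early genes, which respond rapidly to cell stimulation, 7 were higher, among them Npas4 (1.91), Nr4a2 (1.47), Nr4a1 (1.06) and Fos (0.74). Early neuron genes were higher in 6 of 16 cases. These lists passed camera with both correlations (adjusted p = 6.50e-19, 1.91e-06 and 3.41e-05 preset, and 0.0125, 0.0401 and 0.0401 estimated). Adjusted over the list alone, 18, 9 and 7 members passed.

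Marker genes of precursors were compared next. In limma's test no cell cycle, radial precursor, intermediate progenitor or Notch pathway gene passed; Mki67 differed by -0.11 (adjusted p = 0.723), Sox2 by -0.17 (0.428) and Pax6 by -0.17 (0.574). Some members passed under an alternative. Pcna (-0.15, adjusted p = 0.0743) passed with cyclic loess (0.0393). Without neuron replicate 2, Pcna (0.0466), Mcm6 (0.0349), Dll1 (0.0123) and Mfng (0.0468) passed, all lower. Hes6 (-0.19, adjusted p = 0.0522) and Jag2 (0.26, adjusted p = 0.0529) passed without neuron replicate 1 (0.0415 and 0.0323), and Jag2 also without neuron replicate 3 (0.0486) or precursor replicate 1 (0.0402). As lists, cell cycle (median -0.12), radial precursor (median -0.11), intermediate progenitor (median -0.10) and Notch pathway (median -0.053) shifted down with the preset correlation (adjusted p = 2.50e-06, 2.59e-04, 0.0333 and 0.0244). With an estimated correlation they did not (adjusted p = 0.569, 0.325, 0.443 and 0.217). Adjusted over the list alone, 0, 0, 1 and 2 of their members changed, and at an unadjusted p under 0.05 limma gave 2, 1, 3 and 4 lower and 0, 0, 1 and 3 higher. The medians stayed below 0 with cyclic loess. Against the predicted mixture the same lists had medians of 0.088, 0.034, 0.022 and 0.033 and did not shift (camera, preset correlation, adjusted p = 0.305, 0.944, 0.925 and 0.695). The falls from the precursor level were thus not past those that mixing at the estimated neuron share predicts. That share was taken in part from genes at least 4-fold higher in precursors, among them Mki67 (7.77-fold) and Pax6 (4.08-fold) of these lists. The match is therefore no independent evidence that mixing accounts for the falls. Receptors of neurotrophins and GDNF were higher in 4 of 9 cases, with Ntrk2 at 0.95 and Gfra2 at 0.53 (4 changed adjusted over the list alone; adjusted p = 9.36e-04, and adjusted p = 0.203 with an estimated correlation). FGF, EGF, PDGF, IGF and VEGF ligands were higher in 7 of 29 cases, 7 also adjusted over the list alone, with Fgf12 at 0.79 and Nrg3 at 0.71 (adjusted p = 0.0487, and adjusted p = 0.520 with an estimated correlation). Ifngr2 differed by 0.35 and Lifr by 0.31. Ntrk3 differed by 0.20 (adjusted p = 0.0346), but did not pass with cyclic loess (0.0665), without the filter (0.0841), or without any 1 array other than neuron replicates 2 and 3 and precursor replicate 2 (0.0505 without neuron replicate 1, 0.111 without precursor replicate 1 or 3, and 0.0795, 0.155 and 0.0843 without co-culture replicates 1 to 3). Wnt7b differed by 0.27, with adjusted p = 0.0810, and passed with the replicate block (0.0302), without neuron replicate 2 (0.0495) and without precursor replicate 1 (0.0463).

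In all, 1069 genes were higher and 26 lower than in precursors, and 53 and 0 of these at least 2-fold. The lower genes were led by Mir101c (-0.68; adjusted p = 0.0103, and 0.0510 without co-culture replicate 2) and Olfr1085 (-0.56), from families whose probe sets can pick up related copies. With the replicate block 42 were lower. The lower count was 52 without neuron replicate 2, 14 without precursor replicate 2, 7 without co-culture replicate 1 and 10 without co-culture replicate 2, and the higher count was 676 without co-culture replicate 2. With each array centred on its median, 692 genes were higher and 98 lower, so that 87.6% of the calls were higher in place of 97.6%.

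**Figure D3:**
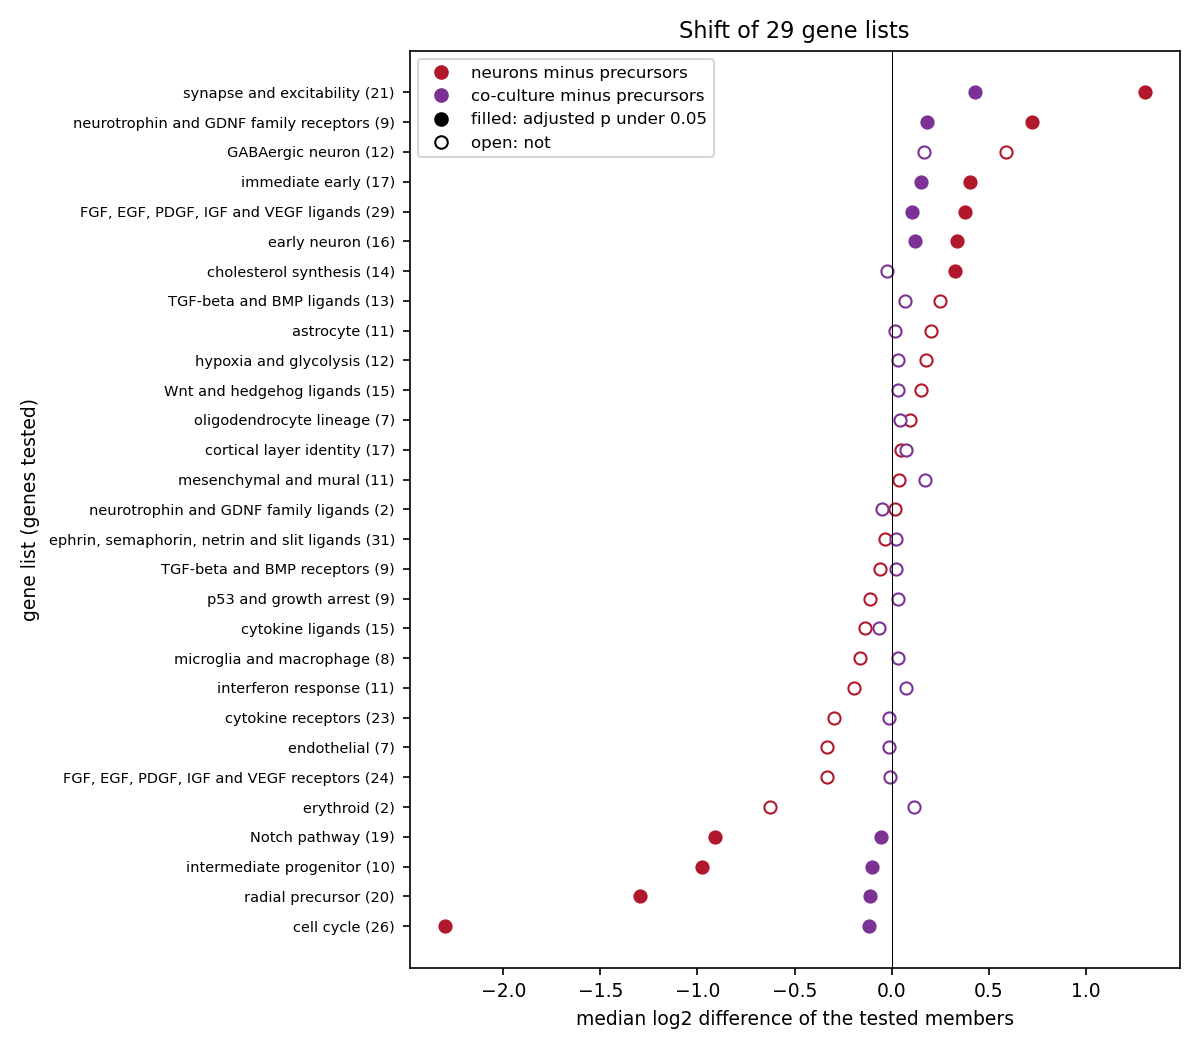
Median log2 difference (horizontal axis) of the tested members of 29 gene lists, with the number tested in brackets, for neurons minus precursors and co-culture minus precursors; filled points passed camera at the preset correlation. Cell cycle genes have a median of -2.30 in neurons and -0.12 in the co-culture, and synapse genes 1.30 and 0.43.

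Against neurons, the co-culture was higher for 4643 genes and lower for 3236, 555 and 297 of these at least 2-fold. All 26 cell cycle genes were higher (median 2.18), as were 19 of 20 radial precursor genes (median 1.17) and all 10 intermediate progenitor genes, and Notch pathway genes were higher in 13 of 19 cases and lower in 3; 20 of 21 synapse genes were lower (median -0.85). H1f5 was 23.7-fold, Ccl3 14.9-fold and Top2a 7.83-fold higher in the co-culture, and Sla, Ntsr1 and Rasgrf2 were 4.04-fold, 3.76-fold and 3.82-fold lower. Early neuron genes were lower in 12 of 16 cases and higher in 1, cholesterol synthesis genes lower in 11 of 14, receptors of neurotrophins and GDNF lower in 6 of 9 and higher in 1, and FGF, EGF, PDGF, IGF and VEGF ligands lower in 18 of 29 and higher in 5. Adjusted over the list alone, 26, 19, 10, 16, 21, 13, 12, 8 and 24 members of these 9 lists changed, in the order given. All 9 passed camera with the preset correlation (adjusted p = 1.75e-13, 7.95e-08, 6.88e-04, 0.00831, 1.38e-09, 7.73e-04, 4.07e-04, 0.00831 and 0.00831). With an estimated correlation only synapse and excitability passed (adjusted p = 0.0401); the others had adjusted p = 0.286, 0.203, 0.237, 0.172, 0.0652, 0.586, 0.286 and 0.325. Centring each array on its median moved the median difference of all genes from 0.032 to -0.080 and gave 3478 higher and 4925 lower genes, 41.4% higher in place of 58.9%.

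No gene lay above or below both separate cultures in the co-culture (limma, adjusted p under 0.05). At an unadjusted one-sided p under 0.05, 141 genes lay above both and 127 below. The smallest adjusted p above both was 0.172, for Apcdd1, an inhibitor of Wnt signalling, and that below both was 1. Apcdd1 had means of 8.36 in neurons, 8.54 in precursors and 8.87 in the co-culture, and passed with the filter at the 75th percentile (1 gene). Without co-culture replicate 3, 1 other gene passed, Fst, which encodes the activin-binding protein follistatin.

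The neuron share of the co-culture RNA was 16.8% ± 1.14 (SD, n = 3). It is an apparent share of RNA like that of the neuron culture. It need not be the share made by neurons, since Tubb3, a marker of young neurons, was at 11.96 in the precursor cultures. Genes at least 4-fold higher in neurons (105 genes) gave 22.6% ± 1.20 and genes at least 4-fold higher in precursors (109 genes) gave 10.97% ± 2.24. At 16.8%, 47 genes lay above the predicted mixture and 4 below, none by 2-fold or more. Those above were led by Fst (log2 departure 0.88, SE 0.097, adjusted p = 0.00842), Nr4a3 (0.87), Necab1 (0.84), Npas4 (0.79), Rgs4 (0.65) and Nr4a2 (0.61). Rgs4 did not pass with the spread of the separate cultures (adjusted p = 0.196) or with a share specific to each gene's direction (0.640), alternatives chosen after seeing the data. With that share the departures of Necab1, Rgs4 and Nr4a2 were 0.49, 0.39 and 0.40. Fst was at 8.10 in neurons, 7.50 in precursors and 8.51 ± 0.26 in the co-culture, where replicate 3 was lowest at 8.21. Those below were Mir101c, Olfr214, Olfr1085 and Olfr1077-ps1, none of which passed with the spread of the separate cultures (adjusted p = 0.196, 0.0939, 0.161 and 0.0861) or with a share specific to each gene's direction (0.0891, 0.0993, 0.0993 and 0.0714). The count below was also 0 without the filter, with cyclic loess, with centred arrays, without neuron replicate 1 or 3, without precursor replicate 2 and without co-culture replicate 1 or 2. It was 1 without neuron replicate 2 or precursor replicate 1, with the filter at the 75th percentile or at a share higher by 0.1. It was 2 with the replicate block, without precursor replicate 3 and without co-culture replicate 3, 9 with array weights and 12 at a share lower by 0.1. Immediate early genes (6 of 17 above), early neuron genes (1 of 16), synapse genes (0 of 21, and 13 at an unadjusted p under 0.05) and cortical layer genes (1 of 17) shifted up as lists with both correlations (adjusted p = 1.38e-09, 0.00864, 1.47e-08 and 0.00836 preset, and 3.54e-07, 3.57e-04, 3.17e-04 and 0.0401 estimated). Adjusted over the list alone, 8, 4, 12 and 1 of their members lay above. Against the mixture the estimated correlation was taken as known, a less strict check than in the comparisons between cultures. It was -0.03 for early neuron genes. Genes high in neurons gave a share of 22.6% and genes high in precursors 10.97%, so both groups lie above a prediction at 16.8% by construction. The median departure of the precursor-high genes was 0.079. With a share specific to each gene's direction, 9 genes lay above the mixture and 0 below. With a share specific to each gene's direction the immediate early list still shifted (adjusted p = 1.93e-09 preset and 4.70e-07 estimated), while early neuron, synapse and cortical layer genes did not pass (adjusted p = 0.175, 0.126 and 0.210 preset, and 0.0796, 0.430 and 0.325 estimated). Lists were also compared with 10000 gene sets matched on the difference of neurons from precursors and on the precursor level. The median departures of immediate early (0.15) and synapse genes (0.16) were higher (matched-set resampling, adjusted p = 0.00167 and 0.001). Those of early neuron (0.056) and cortical layer genes (0.074) did not pass (adjusted p = 0.163 and 0.132). The 6 immediate early genes above became 2 with a share specific to each gene's direction or with centred arrays, 3 with the spread of the separate cultures or without any 1 co-culture array, and 0 at a share higher by 0.1. The single early neuron and cortical layer genes above became 0 and 0 with a share specific to each gene's direction. Cholesterol synthesis genes, 0 of 14 of which passed singly over all genes or adjusted over the list alone (3 lower and 1 higher at an unadjusted p under 0.05), shifted down as a list (median -0.069, adjusted p = 4.08e-06), but not with an estimated correlation (adjusted p = 0.286). The list median lay below that of the matched sets (matched-set resampling, adjusted p = 0.001). Matched sets were drawn gene by gene, so their p-values leave out correlation within a list, estimated at 0.56 for cholesterol synthesis. For all lists these p-values measure the spread between genes, not between cultures. The count above depends on the share: it was 566 at a share lower by 0.1 and 2 at a share higher by 0.1. Leaving out neuron replicates 1 to 3 gave 27, 25 and 18, precursor replicates 1 and 2 gave 25 and 18, and co-culture replicates 1 to 3 gave 10, 9 and 14; the replicate block gave 25, cyclic loess 20, centred arrays 9, and the spread of the separate cultures 10.

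**Figure D4:**
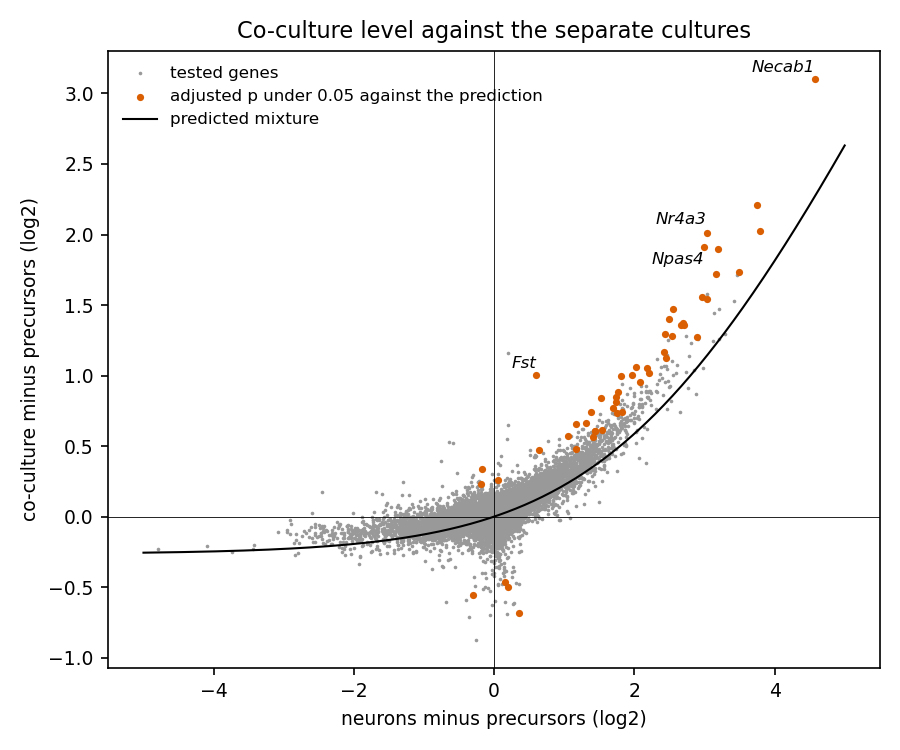
Co-culture minus precursors (vertical axis, log2) against neurons minus precursors (horizontal axis, log2) for the tested genes; the line is the level predicted for a neuron share of 16.8%, and orange points have an adjusted p under 0.05 against it. Of these points 47 lie above the line and 4 below.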

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

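The alternatives that took the spread from the separate cultures alone or a share specific to each gene's direction, and the matched sets for lists, were chosen after seeing the data. Centred arrays turned the majority in co-culture against neurons, with 3478 genes higher and 4925 lower in place of 4643 and 3236, and in neurons against precursors, with 4189 higher and 4081 lower in place of 3637 and 4574. Some list medians near 0 changed sign with scaling, among them ephrin, semaphorin, netrin and slit ligands in neurons against precursors (-0.032, and 0.035 with cyclic loess) and cortical layer genes in co-culture against neurons (0.10, and -0.011 with centred arrays). Of the named genes' results, lists left out, 412 with cyclic loess kept their side of the threshold, 6 lost it and 3 gained it; 406 kept it and 15 lost it without the filter; 415 kept it and 2 lost it with the mean of probe sets; and leaving out single arrays kept 3657, lost 111 and gained 21. The comparison of neurons with precursors kept its counts of higher and of lower genes within 1.5 times under every alternative except the 2-fold limit, and where an alternative's construction does not show the reason for a change, the cause was not tested. Deposited values carry no detection calls, so signal over background was not assessed here and folds of dim genes can be understated.

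The 2-fold limit, stricter by construction, left 715 higher and 624 lower genes in neurons than precursors, 53 and 0 in co-culture than precursors, 555 and 297 in co-culture than neurons, 1352 differing among the 3 cultures, and 0 above and 0 below the predicted mixture. An adjusted p under 0.01 left 641 genes higher and 4 lower in co-culture than precursors, and 14 above and 0 below the mixture. Without the filter, 40 genes were lower in co-culture than precursors, and 19 lay above and 0 below the mixture. With the filter at the 75th percentile these counts were 43, 79 and 1, and 1 gene lay above both separate cultures. Cyclic loess gave 20 above and 0 below the mixture. Centred arrays gave 692 higher and 98 lower in co-culture than precursors, and 9 above and 0 below the mixture. A trended robust variance gave 41 lower in co-culture than precursors and 75 above the mixture. Array weights gave 87 lower, and 90 above and 9 below the mixture. Fits to only the 2 groups compared gave 57 lower in co-culture than precursors.

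With the replicate block, which pairs precursor and co-culture arrays, 42 genes were lower in co-culture than precursors, and 25 lay above and 2 below the mixture. The replicate block moved no other count by over 1.5 times. Of the results for named genes and lists, 526 kept their side of the threshold with it, 5 lost it and 6 gained it; the counts of shifted lists did not change. Apart from Wnt7b and the count above, those in co-culture against precursors were Cdkn1a (adjusted p = 0.0280), Cxcl12 (0.0244) and Trp53inp1 (0.0283), which gained it, and Gdf10 (0.0752), Inhba (0.0565), Olfr824 (0.0655), Tnfrsf21 (0.0781) and Vmn1r91 (0.0710), which lost it. Where neurons are compared, arrays share only a number, and Ret in co-culture against neurons (0.0114) and Olig1 in neurons against precursors (0.0204) gained it.

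Genes at least 8-fold different gave a neuron share of 18.8%. A share lower by 0.1 gave 566 genes above and 12 below the mixture, a share higher by 0.1 gave 2 and 1, and a share of 0.5 gave 2754 and 1625. The share specific to each gene's direction gave 9 above and 0 below, and all 9 were among the 47; 2 lists shifted against the mixture with it in place of 5. With the spread of the separate cultures 706 genes were higher and 14 lower in co-culture than precursors, and 10 lay above and 0 below the mixture, all 10 among the 47. With an estimated correlation 1 list shifted in neurons against precursors, 3 in co-culture against precursors and 1 in co-culture against neurons, in place of 10, 9 and 9; fry, which does not compare a list with other genes, gave 21 and 19 for the comparisons with neurons.

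Leaving out each array in turn gave 3381 to 3696 higher and 4209 to 4618 lower genes in neurons than precursors, 676 to 1138 higher and 7 to 52 lower in co-culture than precursors, 4200 to 4700 higher and 2856 to 3376 lower in co-culture than neurons, and 7388 to 8068 differing among the 3 cultures. Genes above both separate cultures numbered 0 to 1 and below both 0. Genes above the mixture numbered 9 to 41 and below it 0 to 2, and the share was 16.3% to 17.6%. The lower count in co-culture than precursors was 52 without neuron replicate 2, 14 without precursor replicate 2, 7 without co-culture replicate 1 and 10 without co-culture replicate 2, and the higher count was 676 without co-culture replicate 2. Above the mixture were 27, 25 and 18 genes without neuron replicates 1 to 3, 25 and 18 without precursor replicates 1 and 2, and 10, 9 and 14 without co-culture replicates 1 to 3. Below it were 0, 1 and 0 without neuron replicates 1 to 3, 1, 0 and 2 without precursor replicates 1 to 3, and 0, 0 and 2 without co-culture replicates 1 to 3.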

Other observations

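These tests were chosen after the results were seen: those on median polish, on co-cultures that varied less, on a mixture with one share, on log-scale summarization, on a departure shared by neuron-high genes and on a medium change, and the regroupings for levels above and below both cultures.

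Among other gene groups, immediate early genes were higher in neurons than precursors in 11 of 17 cases and lower in 6 (adjusted p = 0.0399, and adjusted p = 0.286 with an estimated correlation), and cholesterol synthesis genes higher in 10 of 14, with Mvd at 0.89 and Pmvk at 0.78 (adjusted p = 0.00363, and adjusted p = 0.721 with an estimated correlation). Cortical layer genes differed in both directions, with 7 of 17 higher in neurons, among them Ldb2 (2.49), Mef2c (2.46) and Rorb (1.00), and 8 lower, among them Tbr1 (-0.94). GABAergic neuron genes were higher in 7 of 12 cases, with Sst at 1.40 and Maf at 1.34, and lower in 5, with Calb2 at -1.16. In these 4 lists 17, 11, 15 and 12 genes changed adjusted over the list alone, and cortical layer and GABAergic neuron genes did not shift as lists (adjusted p = 0.860 and 0.535). Ephrin, semaphorin, netrin and slit ligands were higher in 12 and lower in 12 of 31 cases, 24 adjusted over the list alone, with Sema7a at 1.30 and Efnb1 at -1.35; their median was -0.032, their mean 0.075 and camera's direction up (adjusted p = 0.680), and the median was above 0 with cyclic loess and with centred arrays. TGF-beta and BMP ligands were higher in 7 and lower in 3 of 13 cases, 10 adjusted over the list alone, with Inhba at 1.99 (adjusted p = 0.305), and their receptors higher in 4 and lower in 4 of 9, 8 adjusted over the list alone, with Tgfbr1 at -0.98 (adjusted p = 0.966; median -0.058 and mean -0.13, camera's direction up). Cytokine receptors were lower in 13 and higher in 5 of 23 cases, 18 adjusted over the list alone (adjusted p = 0.377), and Wnt and hedgehog ligands higher in 4 and lower in 3 of 15, 7 adjusted over the list alone, with Rspo2 at 1.11 (adjusted p = 0.498). Of the ligands of the neurotrophin and GDNF families 2 were tested, with 0 past limma's threshold or adjusted over the list alone, and 0 at an unadjusted p under 0.05 (adjusted p = 0.944).

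Markers of other cell types did not shift as lists between neurons and precursors. Astrocyte genes were higher in 5 and lower in 4 of 11 cases, with Sparcl1 at 2.33 and Aldoc at -1.78 (adjusted p = 0.860). Endothelial genes were lower in 5 of 7, with Cdh5 at -1.21 (adjusted p = 0.148), and oligodendrocyte lineage genes higher in 1, Lhfpl3, and lower in 1 of 7 (adjusted p = 0.572). Mesenchymal and mural genes were higher in 2, Tagln and Acta2, and lower in 2 of 11 (adjusted p = 0.888), and the erythroid gene Hbb-y was lower at -1.30, with 2 tested (adjusted p = 0.860). Adjusted over the list alone 10, 5, 1, 4 and 1 genes changed in these lists. Genes of p53 and growth arrest (2 higher and 3 lower of 9, adjusted p = 0.834), interferon response (3 and 4 of 11, adjusted p = 0.852) and hypoxia and glycolysis (6 and 4 of 12, adjusted p = 0.792) did not shift either, and 5, 8 and 10 of them changed adjusted over the list alone. Sesn2 (-1.22), Usp18 (-1.53), Rsad2 (-1.02) and Slc2a1 (-1.11) were lower and Pfkp (1.11) higher in neurons.

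Co-culture arrays varied less than the others, with a median SD of 0.055 against 0.066 in precursors and 0.083 in neurons, and 164 genes had the same co-culture value on all 3 arrays to within 1e-06. Among genes whose 3 groups do not overlap, precursors as the middle group (122 genes) had 0.389 times the SD they had as an outer group (bootstrap interval 0.322 to 0.461), below the 0.694 to 0.831 of 200 simulations with equal noise, and the co-culture had a ratio of 0.819 against 1.06 to 1.28. A robust summary over probes, such as the median polish of RMA, that holds the middle group together could give this. The measured SDs were unequal between groups, unlike in the simulations. Picking separated genes under unequal noise could therefore also lower these ratios, which was not tested. In 1493 genes that did not differ among groups, the co-culture SD was 0.955 times that of precursors (0.871 to 1.05), so whether the co-cultures themselves varied less stays open. Probe-level values were not analysed here, and p-values for the co-culture may be too small: 706 in place of 1069 genes were higher than in precursors with the spread of the separate cultures.

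The apparent neuron share differed between genes high in neurons and genes high in precursors by 11.6 percentage points. The gap was more than its SD over arrays and had the same sign on all 3. Linear mixing of these gene-level values at a single share would not give this gap. Whether 2 unchanged cultures were mixed cannot be told from it, because summarization on the log scale (below) may part the 2 shares. Compression of bright values would give brighter precursor-high genes a lower share, but the brightest (36 genes) gave 11.2% and the dimmest (37 genes) 8.81%, a difference of 2.41 points (permutation p = 0.024, two-sided, 10000 permutations). Summarization on the log scale over probes with unequal ratios stays open, since the median departure of 0.079 in precursor-high genes cannot be traced to probes here. A change of either cell type in co-culture also stays open and was not tested separately. The same holds for a difference in time in culture between the neurons alone and those in co-culture, on which the labels conflict.

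Of 17 immediate early genes 6 lay above the predicted mixture. The 11 that were higher in neurons had a median departure of 0.34, at percentile 100 of 10000 sets matched on the difference and the precursor level. The matched sets had a median of 0.081 (0.018 to 0.15). The one-sided p of this matched-set resampling was 0.0001, the smallest these sets can give. This argues against a departure shared by all neuron-high genes. The resampling p measures the spread between genes, not between cultures. At a share of 16.8%, an understated spread as the whole cause is argued against by 3 of 17 (Fos, Npas4 and Nr4a2). These still passed with the spread of the separate cultures, in place of 6. With a share specific to each gene's direction Npas4 and Nr4a2 passed (limma, adjusted p = 0.0154 for each) and Fos did not (0.0721). Spread and share were not changed together. The count was 2 with a share specific to each gene's direction or with centred arrays, 4 with cyclic loess or the replicate block, 3 to 5 without single arrays and 0 at a share higher by 0.1, where the median departure was 0.18. A response of either cell type to co-culture is a hypothesis only. Plating or a medium change when precursors were added may give the same rise. That stays open because 0 arrays of neurons given medium alone were analysed here. One label gives 4 days and another 5 days in total for the neurons alone. If 4 days holds, they had spent less time in culture than the co-cultured neurons, a difference that was not tested.

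Other splits of the arrays were counted for each set of calls. For neurons against precursors (7770 genes with only these 6 arrays) and co-culture against neurons (7632), 1 of 10 splits, the real one, gave as many and the highest other gave 0; for co-culture against precursors (1161) it was 1 of the 4 splits that part all 3 same-numbered pairs, with 0 the highest other. These splits are too few for a share under 0.05. For genes differing among the 3 cultures, 1 of 100 splits, the real one, gave 7984 and the highest other 7527, so chance was excluded for this count. Since another grouping came near it, the count does not show that each culture differs from both others. For genes above both cultures (0, highest other 2929) and below both (0, highest other 4383), 100 of 100 regroupings gave as many, which a count of 0 fixes beforehand, so these regroupings show nothing about chance. Chance was not excluded for genes away from the predicted mixture, where 5 of 100 regroupings gave at least the 51 found and the highest other gave 8419. Why some regroupings gave several times the real count was not tested.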
